A study of Rattus norvegicus with 12 samples.

How the data were processed

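Two-channel rat oligonucleotide arrays were deposited for 12 RNA samples of F11 cells, 3 for each of 4 times of forskolin, each hybridised against the same kind of unstimulated reference. Total RNA had been extracted with Trizol and labelled with an Agilent kit, per the labels' protocols. The arrays were scanned and quantified with Feature Extraction 9.5.1.1, per the file headers, and each deposited file gives for 45018 spots the mean intensity of the spot and the median intensity of its local background in green (Cy3, forskolin) and red (Cy5, reference). The same files hold the processed intensity of each channel, background-subtracted, detrended and dye-normalized within the array by linear and lowess steps, per the file headers. The series matrix holds the authors' log2 values. The submitters' processing notes name limma (version not given), and the normalization behind these values is not given in the sources used here. Set against the scanner values of the same array over bright spots, the deposited log2 values correlated at 0.938 to 0.988 with slopes of 0.913 to 1.008 and ran as red over green, opposite to the direction used here. Their column medians were 0.007 to 0.012, and 170 non-control spots were absent from them.

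Of the 43379 non-control spots, which carried 41012 distinct probes, names were updated through a list of RefSeq genes of the GRCr8 assembly. Of the probes, 10735 were named by accession, 5571 had a current symbol, 83 matched another accession, 1026 matched a synonym and 23597 kept the file's name, for 35554 genes or unnamed transcripts. Coordinates are those of the files, whose headers name build rn3, and 124 of the 129 named genes had a probe with a position. No genome of that build was used here.

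Mean intensities were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, with version 1.17.8 of data.table, and the log2 ratio of green over red was normalized within each array by loess, with control spots at weight 0. Spots with an outlier flag were left out and spots of a probe averaged. A probe was kept if it was well above background in at least 1 channel on all 3 arrays of at least 1 time point, which left 20439 probes, and the brightest probe stood for a gene, giving 17657 genes. In 2325 genes with several kept probes, 66, 249, 117 and 104 had probes called in opposite directions at 2, 4, 24 and 48 h. Median signals were 64.6 to 71.5 in green over a local background of 47 to 52, and 112.7 to 127.9 in red over 83 to 88, so that most probes are dim and their changes are compressed towards 0.

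A linear model with a mean for each time point was fitted to the 12 arrays (8 residual degrees of freedom) with lmFit and eBayes. Each mean was tested against 0, the 4 means against each other by F, successive time points against each other, and the mean of 24 and 48 h against that of 2 and 4 h, with Benjamini-Hochberg adjustment over the genes of each comparison and calls at an adjusted p under 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 95 tests of 19 lists, and again with an estimated correlation. Where a gene's channel was well above background on none of the arrays of a group, a bound is given in place of a fold.

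The genes named were chosen before the data were examined: among called genes with a symbol and the same sign on all 3 arrays, the 8 largest rises and the 8 largest falls at each time point and for late against early, the 5 largest each way for successive time points, up to 4 called members per list with the largest change, and 12 genes always given. Other list members are named as examples of their list and were picked after their values were seen. The lists were cAMP-responsive early genes, cAMP pathway components, neuropeptides and secretory granule, regeneration-associated genes, neuronal cytoskeleton and synapse, sensory neuron genes, cell cycle, cholesterol and fatty acid synthesis, ER stress and amino acid response, heat shock, C/EBP and PAR bZIP factors and circadian clock, hypoxia and glycolysis, actin, SRF and YAP targets, quiescence and FoxO targets, glial markers, fibroblast and matrix markers, leukocyte and endothelial markers, ribosomal proteins and housekeeping genes. None was drawn from these samples, and some genes stand in more than 1 list.

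The fit and its calls were tested on log2 ratios drawn independently around 0 with each gene's fitted spread. Background correction, loess, the filter and the choice of probes were not part of that simulation, so it leaves out the compression of dim probes. Of 100 genes changed by 0.5 on the log2 scale, 97% were recovered for 24 h against the reference and 92% for 24 h against 4 h; at a change of 1, 100% and 99% were recovered, and 8 and 14 unchanged genes were called. When the green channel of 300 genes with bright probes was doubled in a copy of the data, which was then normalized again, all 300 moved up, by a mean of 1.00. Alternatives tried were no background correction, normexp with offset 0, median centring, Aquantile scaling between arrays, Agilent's processed signals, the series matrix values, no filter on dim probes, a stricter filter, the mean of all probes of a gene, an intensity trend with robust eBayes, fits on the compared arrays alone, the replicate number (here also the slide) as a block, an estimated inter-gene correlation, and leaving out each array. The setting without background correction kept the offset of 50, so its smaller changes cannot be put down to the missing correction alone. Aquantile scaling changes intensities and leaves each log2 ratio as it is, so it gave the same values and tests nothing here.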

Results

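Gene expression was followed in F11 cells, a hybrid line made by fusing rat dorsal root ganglion neurons with mouse neuroblastoma cells and used as a culture model of sensory neurons. How far mouse transcripts bound the rat probes could not be worked out, so a change may be that of rat copies, mouse copies or both. The cells were kept for 3 h in medium with 0.5% serum and then given 10 µM forskolin, a plant diterpene that activates adenylyl cyclases and so raises cyclic AMP. RNA was collected after 2, 4, 24 and 48 h of forskolin, with 3 samples per time point and 12 in all. Each sample was hybridised to a rat array together with a common reference, which was RNA of F11 cells after the same 3 h in low serum without forskolin. The design asked how transcription changed over time after cyclic AMP was raised in neuron-like cells. Forskolin RNA carried Cy3 and reference RNA carried Cy5 on all 12 arrays. A dye effect peculiar to a gene therefore stays in every change against the reference and cancels between time points. The reference counted as 1 control sample, which leaves out the spread between control cultures. In addition, 0 arrays held cells kept in low serum for as long without forskolin. On each array, 19889 to 21973 of the 43379 non-control spots were well above background in the forskolin channel and 19504 to 23285 in the reference channel. The 3 arrays per time point limit the precision. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. All changes are log2 ratios of forskolin over reference, given with the SD over n = 3 arrays, and calls are Benjamini-Hochberg adjusted p-values under 0.05 in limma over 17657 genes. Bright probes leaned towards the reference channel before the loess step. With each array only centred on its median, the brightest 5% of probes lay 1.12 to 1.72 log2 units below the dimmer ones. The median of all tested genes was -0.58 at 2 h, -0.59 at 4 h, -0.45 at 24 h and -0.46 at 48 h, whereas after loess it was -0.025, -0.035, -0.025 and -0.019. Directions of many changes against the reference therefore rest on the loess step. Among the genes of the lists and those followed here, values of up to 1.46 (Chgb at 48 h) lost their direction with median centring, and of up to 0.92 (Prph at 48 h) relative to that median. Flips relative to that median are given for the gene lists and for the genes followed over all time points.

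After 2 h of forskolin, the largest rises included genes known to respond to cyclic AMP. Bhlhe41, a transcriptional repressor of the circadian clock, rose 9.21-fold (log2 change 3.20 ± 0.06, SD, n = 3, adjusted p = 2.2e-14). Fst, which encodes the activin-binding protein follistatin, rose 7.37-fold (2.88 ± 0.05), and Rgs2, a regulator of G protein signalling, rose 6.87-fold (2.78 ± 0.12). The antiproliferative gene Btg2 (2.70 ± 0.15), the orphan nuclear receptor genes Nr4a3 (2.53 ± 0.18) and Nr4a1 (2.22 ± 0.10), and the kinase genes Sik1 (2.47 ± 0.26) and Sgk1 (2.19 ± 0.12) followed. The zinc-finger gene Egr1, itself an immediate-early gene, went the other way and fell 3.25-fold (-1.70 ± 0.08, adjusted p = 1.1e-10). With no unstimulated cells at 2 h, it cannot be told whether forskolin lowered Egr1 or the reference still responded to the medium change. The other largest falls were smaller: the Wnt antagonist gene Dkk1 (-0.91 ± 0.07), the transcription factor gene Klf6 (-0.84 ± 0.10) and the synaptic immediate-early gene Arc (-0.73 ± 0.14). Other falls were in the ribosomal protein genes Rps23 (-0.75 ± 0.13) and Rpl8 (-0.68 ± 0.15), Smpdl3a (-0.68 ± 0.09) and the mitochondrial carrier gene Slc25a27 (-0.66 ± 0.16). The adjusted p-values of these falls were 6.9e-05 or smaller. In the files' rn3 coordinates the Fst probe lies on chromosome 2 from 46471460 to 46471519, the Egr1 probe on chromosome 18 from 27373819 to 27373878 and the Rgs2 probe on chromosome 13 from 57905038 to 57905097. No annotation of that build was used here.

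Of the 25 measured cAMP-responsive early genes, 18 rose, 3 fell and 4 were not called at 2 h (median 1.07). In all, 23 were called when adjusted over the list alone (camera adjusted p = 2.5e-18, and adjusted p = 0.013 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, rose by 2.04, Junb by 1.78, Klf4 by 1.66 and Fos by 1.22, whereas Egr1, Arc and Homer1 were the 3 that fell. Among 18 genes of the C/EBP and PAR bZIP factors and the circadian clock, 8 rose, 1 fell and 9 were not called (median 0.10). In all, 12 were called when adjusted over the list alone (for the list, adjusted p = 7.8e-04, and adjusted p = 0.035 with an estimated correlation). Bhlhe41, Cebpb (1.07 ± 0.16), Nfil3 (0.66 ± 0.00) and Bhlhe40 (0.51) led that group, and Cry1 fell (-0.17). Nfil3 and Per1 stand in both lists. Of 28 genes of ER stress and the amino acid response, 12 rose, 1 fell and 15 were not called (median 0.11). In all, 14 were called when adjusted over the list alone (for the list, adjusted p = 7.7e-06), among them the protein disulfide isomerase gene Pdia3 (0.44) and the chaperone gene Calr (0.40). That call was lost with an estimated correlation (adjusted p = 0.051). With median centring Pdia3 (-0.09) and Calr (-0.17) lay below the median of all genes, and the list's median lay 0.27 below that of all genes with median centring (-0.27). Without background correction the median of the early genes was 0.69, and with the processed signals that of the C/EBP list was 0.21 and that of the ER stress list 0.18. The vasodilator peptide gene Adm rose by 1.95 (± 0.07) and the antiproliferative gene Tob1 by 1.52 (± 0.15) outside the lists called at this time.

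In all, 5058 genes were called at 2 h, 1785 higher and 3273 lower, of which 49 were at least 2-fold higher and 2 at least 2-fold lower. The 2-fold counts depended on the scaling: 141 higher and 169 lower with Agilent's processed signals, 79 and 16 with offset 0, 36 and 1 without background correction, and 13 and 4552 with median centring. The 4 arrays of a slide held the 4 time points of a replicate number. On all 3 slides 2 h stood at position 1, 4 h at position 2, 24 h at position 3 and 48 h at position 4. An effect of array position therefore cannot be told apart from time, with or without the slide as a block. With the slide as a block 6221 genes were called, and 4994 of the 5058 (98.7%) had the same sign on all 3 slides. The genes were called from these same arrays, which favours equal signs. Such shares, here and for the later comparisons, are therefore no separate support for the calls. The count was 2821 without 2 h replicate 3 and 3188 without 2 h replicate 2. With median centring it was 13759, of which 1.66% were higher in place of 35.3%.

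After 4 h, Fst had risen 34.1-fold (5.09 ± 0.05, adjusted p = 4.7e-17) and Rgs2 15.1-fold (3.92 ± 0.01). Sik1 (3.47 ± 0.16) and Nr4a3 (3.30 ± 0.13) stood above 9-fold, as did Tac1, the precursor gene of substance P (3.27 ± 0.11), and Crem, which encodes activators and repressors binding the cAMP response element (3.20 ± 0.05). The neuropeptide gene Vip rose 6.13-fold (2.62 ± 0.05) and Nr4a1 5.85-fold (2.55 ± 0.12). Egr1 fell 8.07-fold (-3.01 ± 0.10, adjusted p = 1.5e-13), and Klf10, a gene induced by TGF-beta, fell 5.87-fold (-2.55 ± 0.07). The pro-apoptotic gene Bbc3 (-2.11 ± 0.05), Dkk1 (-1.91 ± 0.08), Enc1 (-1.59 ± 0.09), Arc (-1.59 ± 0.07), the adaptor gene Dok4 (-1.51 ± 0.04) and the cytokine gene Csf1 (-1.40 ± 0.05) were the other largest falls, with adjusted p-values of 7.7e-10 or smaller. Other probes of some of these genes gave smaller changes: 0.16 to 2.58 for Nr4a3, -0.55 for Klf10, -0.47 for Enc1 and -0.59 for Csf1.

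At 4 h, 15 of the 25 cAMP-responsive early genes had risen, 6 had fallen and 4 were not called (median 0.28). In all, 22 were called when adjusted over the list alone (for the list, adjusted p = 2.0e-04, but adjusted p = 0.23 with an estimated correlation). The median was 1.15 with the processed signals, and 0.58 relative to all genes with median centring. Btg2 (0.97), Dusp1 (0.85) and Fosl2 (0.87) were among those that rose, while Ier2 (-1.02), Atf3 (-0.78 ± 0.05), Homer1 (-0.63) and Junb (-0.28) were among those that fell, beside Egr1 and Arc. Of 25 genes of neuropeptides and the secretory granule, 10 rose, 6 fell and 9 were not called (median 0.09). In all, 16 were called when adjusted over the list alone (for the list, adjusted p = 0.035). Tac1, Vip and the granin gene Scg2 (1.39) rose, and Npy (-0.62) and Calca, the gene of calcitonin and CGRP (-0.21), fell. This list's call was lost with an estimated correlation (adjusted p = 0.26) and without background correction (adjusted p = 0.074), and its median lay at -0.07 relative to all genes with median centring and at 0.18 with the processed signals. The phosphodiesterase genes Pde4d (1.86 ± 0.11) and Pde10a (1.08 ± 0.16) rose among the cAMP pathway components, and Nefl, a neurofilament gene, rose by 1.76 (± 0.05). Ret, the receptor gene for GDNF family ligands, fell by 1.06 (± 0.04), Klf7 by 1.2 (± 0.31) and the insulin receptor substrate gene Irs2 by 0.98 (± 0.11).

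The number of genes called at 4 h was 8835, with 3469 higher and 5366 lower. Of these, 82 were at least 2-fold higher and 69 at least 2-fold lower, against 375 and 715 with the processed signals, 200 and 236 with offset 0, 58 and 41 without background correction, and 27 and 4915 with median centring. With the slide as a block it was 9697, and 8769 of the 8835 genes (99.3%) had the same sign on all 3 slides. With median centring 13903 genes were called, of which 2.32% were higher in place of 39.3%.

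After 24 h, most genes of the cell cycle list had fallen and most of the cholesterol and fatty acid synthesis list had risen. Fst (12-fold, 3.58 ± 0.09) and Vip (8.40-fold, 3.07 ± 0.06) were the genes with the largest rises, with adjusted p-values of 5.1e-15 and 1.1e-14. They were followed by Tmem204 (2.55 ± 0.24), the AMP deaminase gene Ampd3 (2.25 ± 0.11), the aldo-keto reductase gene Akr1b8 (2.21 ± 0.05), Fads3 of the fatty acid desaturase family (2.18 ± 0.09), the peroxisomal acyl-CoA oxidase gene Acox2 (2.14 ± 0.21) and the amino acid transporter gene Slc7a8 (1.96 ± 0.14). Genes of histone H2A fell most: Hist1h2af 5.93-fold (-2.57 ± 0.16), Hist1h2ao (-2.52 ± 0.15), Hist1h2an (-2.31 ± 0.14), H2ac25 (-2.29 ± 0.08) and H2ac18 (-2.18 ± 0.15). These genes are near-identical copies whose probes may have measured each other's transcripts, so their number is uncertain. Egr1 (-2.10 ± 0.02), the chemokine receptor gene Cxcr4 (-1.72 ± 0.14) and the growth factor gene Ptn (-1.70 ± 0.24) completed the largest falls, all with adjusted p-values of 3.4e-08 or smaller.

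Of 41 cell cycle genes, 35 fell, 2 rose and 4 were not called at 24 h (median -0.52). In all, 38 were called when adjusted over the list alone (for the list, adjusted p = 9.0e-13, and adjusted p = 0.011 with an estimated correlation). The ribonucleotide reductase gene Rrm2 fell by 1.44 (± 0.06), the cyclin gene Ccna2 by 1.32 (± 0.05), the spindle checkpoint gene Bub1b by 1.25 (± 0.01) and Mcm3 of the replicative helicase by 1.19 (± 0.08), whereas Ccnd3 and Cdc25b rose (0.31 and 0.37). Of 29 genes of cholesterol and fatty acid synthesis, 25 rose, 0 fell and 4 were not called (median 0.44). In all, 27 were called when adjusted over the list alone (for the list, adjusted p = 9.0e-13, and adjusted p = 0.010 with an estimated correlation). The sterol synthesis genes Msmo1 (1.82 ± 0.06), Hmgcs1 (1.67 ± 0.09) and Fdps (1.51 ± 0.09) and the sterol sensor gene Insig1 (1.45 ± 0.05) rose most. Among 25 neuropeptide and secretory granule genes, 16 rose, 5 fell and 4 were not called (median 0.22). In all, 21 were called when adjusted over the list alone (for the list, adjusted p = 0.0012, but adjusted p = 0.12 with an estimated correlation). Vip, Th, the rate-limiting enzyme gene of catecholamine synthesis (1.5 ± 0.06), Vgf (1.24 ± 0.07) and Scg2 (1.13) rose, while Npy (-0.74) and Pomc (-0.45) fell. With the processed signals the medians of these 3 lists were -0.84 for the cell cycle, 0.71 for cholesterol and fatty acid synthesis and 0.50 for neuropeptides. That of neuropeptides was 0.13 without background correction, and that of the cell cycle -0.94 relative to all genes with median centring.

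Of 28 genes of ER stress and the amino acid response, 15 rose, 2 fell and 11 were not called at 24 h (median 0.22). In all, 17 were called when adjusted over the list alone (for the list, adjusted p = 8.3e-04, but adjusted p = 0.12 with an estimated correlation). Ddit4 (1.44 ± 0.07), Atf5 (1.25 ± 0.06) and Ddit3 (1.02 ± 0.06), which encode stress-responsive regulators, led the rise, and the chaperone gene Hyou1 fell (-0.25). Of 27 genes of hypoxia and glycolysis, 16 rose, 5 fell and 6 were not called (median 0.16). In all, 21 were called when adjusted over the list alone (for the list, adjusted p = 0.0054, but adjusted p = 0.092 with an estimated correlation). The glucose transporter gene Slc2a1 (0.79) and the neuronal enolase gene Eno2 (0.76) rose, and the lactate transporter gene Slc16a3 fell (-0.92 ± 0.06). With median centring the ER stress and hypoxia medians lay below that of all genes, at -0.26 and -0.23, and with the processed signals the hypoxia median was 0.26. Sparc (1.54 ± 0.05) and Pdgfrb (1.08 ± 0.02) rose and Fn1 fell (-1.2 ± 0.04) among the fibroblast and matrix markers, a list that was not called.

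At 24 h, 9502 genes were called, 4302 higher and 5200 lower, with 161 at least 2-fold higher and 122 at least 2-fold lower. The 2-fold counts were 690 and 768 with the processed signals, 334 and 282 with offset 0, 95 and 99 without background correction, and 17 and 3464 with median centring. With the slide as a block 10334 genes were called, and 9421 of the 9502 (99.1%) had the same sign on all 3 slides. With median centring the count was 12971, of which 4.13% were higher in place of 45.3%.

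At 48 h, most genes of the neuronal cytoskeleton and synapse list stood higher and most of the cell cycle list lower than in the reference. Tmem204 (5.74-fold, 2.52 ± 0.16), the argininosuccinate lyase gene Asl (4.90-fold, 2.29 ± 0.15), Lzts1 (2.18 ± 0.09), the gamma-synuclein gene Sncg (2.07 ± 0.10), Il17re (1.96 ± 0.02), Bhlhe41 (1.93 ± 0.06), Lix1 (1.89 ± 0.26) and Ampd3 (1.89 ± 0.10) rose most, with adjusted p-values of 2.2e-10 or smaller. For Ampd3 the reference channel was well above background on 2 of the 3 arrays. Egr1 fell 10.7-fold (-3.42 ± 0.15, adjusted p = 7.8e-14). The H2A genes Hist1h2ao (-2.20 ± 0.20), Hist1h2af (-2.15 ± 0.16), H2ac25 (-1.97 ± 0.03), Hist1h2an (-1.96 ± 0.13) and H2ac18 (-1.91 ± 0.18) remained low, beside the cell cycle repressor gene E2f8 (-2.04 ± 0.16; -0.42 for its other probe) and Pclaf, whose product binds PCNA (-1.84 ± 0.05).

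Of 41 cell cycle genes, 37 fell, 0 rose and 4 were not called at 48 h (median -0.97). In all, 39 were called when adjusted over the list alone (for the list, adjusted p = 2.6e-16, and adjusted p = 0.010 with an estimated correlation), with Rrm2 at -1.82 (± 0.06), Ccna2 at -1.71 (± 0.04) and Bub1b at -1.65 (± 0.06). Of 29 genes of cholesterol and fatty acid synthesis, 25 rose, 1 fell and 3 were not called (median 0.63). In all, 26 were called when adjusted over the list alone (for the list, adjusted p = 4.8e-12, and adjusted p = 0.010 with an estimated correlation), with Hmgcs1 at 1.81 (± 0.17) and Msmo1 at 1.78 (± 0.05); Hsd17b7 was the member that fell (-0.14). Of 34 genes of the neuronal cytoskeleton and synapse, 25 rose, 3 fell and 6 were not called (median 0.37). In all, 28 were called when adjusted over the list alone (for the list, adjusted p = 4.2e-06, and adjusted p = 0.035 with an estimated correlation). The SNARE gene Snap25 (1.47 ± 0.29), the tau gene Mapt (1.19 ± 0.20) and the intermediate filament gene Prph (0.92) rose, whereas the stathmin gene Stmn1 (-0.98 ± 0.05), Elavl2 (-0.66) and Nefh (-0.27) fell. Of 25 neuropeptide and secretory granule genes, 16 rose, 3 fell and 6 were not called (median 0.32). In all, 19 were called when adjusted over the list alone (for the list, adjusted p = 3.3e-04, but adjusted p = 0.092 with an estimated correlation), with the granin genes Chgb (1.46 ± 0.06) and Chga (1.39), Th (1.38 ± 0.04) and Vip (1.32 ± 0.05) among those that rose. Of 25 sensory neuron genes, 13 rose, 2 fell and 10 were not called (median 0.18). In all, 15 were called when adjusted over the list alone (for the list, adjusted p = 0.012, but adjusted p = 0.12 with an estimated correlation). The calcium channel gene Cacna1b (1.29 ± 0.07), the sodium channel gene Scn9a (1.05) and Runx1 (0.75 ± 0.16) rose, and Gfra2 (-0.27) and Calca (-0.13) fell. Relative to all genes, median centring gave a median of 0.21 for the neuronal cytoskeleton and synapse and of 0.41 for cholesterol and fatty acid synthesis, and turned Prph to -0.15. With the processed signals the sensory neuron median was 0.28.

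The 48 h count was 10187 genes, 4793 higher and 5394 lower, with 235 at least 2-fold higher and 232 at least 2-fold lower. The 2-fold counts were 952 and 1024 with the processed signals, 536 and 487 with offset 0, 138 and 190 without background correction, and 15 and 3886 with median centring. With the slide as a block it was 10929, and 9963 of the 10187 genes (97.8%) had the same sign on all 3 slides. With median centring 13150 genes were called, of which 5.44% were higher in place of 47.1%.

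Genes chosen in advance for their place in cyclic AMP signalling or nerve regeneration followed different courses. Crem stood at 1.39 ± 0.20, 3.20 ± 0.05, 1.1 ± 0.14 and 0.63 ± 0.07 at 2, 4, 24 and 48 h, and Cebpb at 1.07 ± 0.16, 1.53 ± 0.20, 1.01 ± 0.26 and 0.59 ± 0.31. Nfil3, a repressor of the bZIP family, rose to 1.09 ± 0.04 at 4 h and 0.33 ± 0.03 at 24 h and was at -0.11 ± 0.05 at 48 h (adjusted p = 0.020, and 0.062 and 0.13 without 48 h replicate 1 and 3). Creb1 rose by 0.30 ± 0.06 at 2 h and fell by 0.43 ± 0.01 at 48 h. Its 4 h value of 0.14 ± 0.06 was not called without 4 h replicate 1 or 2 (adjusted p = 0.071 and 0.16). Atf3 rose at 2 h (0.48 ± 0.05) and lay below the reference at 4 h (-0.78 ± 0.05), 24 h (-0.60 ± 0.06) and 48 h (-1.21 ± 0.08). Nr4a1 stood at 0.11 ± 0.11 at 24 h, which was not called (adjusted p = 0.10, and 0.029 with the slide as a block), and at -0.46 ± 0.03 at 48 h. Fos rose by 1.22 ± 0.10 at 2 h and was at 0.06 ± 0.08 at 4 h, which was not called. At 24 and 48 h its forskolin channel was not well above background, so that Fos was at least 1.19-fold and at least 1.23-fold lower. These bounds set the mean of the bright channel against that of the dim channel, taken per array as the higher of its own signal and the lowest signal well above background, after scaling between arrays, and remain open to dye bias. As the signal of Fos itself was mostly the higher, they hardly differ from the fitted changes. Vgf, a secreted neuropeptide precursor, was at 0.38 ± 0.06, 0.74 ± 0.13, 1.24 ± 0.07 and 0.39 ± 0.01. The growth cone gene Gap43 was not called at 2 h (-0.09 ± 0.15), was lower at 4 h (-0.25 ± 0.14) and 24 h (-0.23 ± 0.10) and higher at 48 h (0.29 ± 0.13). Its 4 h and 24 h calls were each lost without replicate 2 or 3 of that time point (adjusted p = 0.058, 0.061, 0.065 and 0.074). Cebpd was called at 24 h only (0.19 ± 0.11), a call lost without 24 h replicate 2 (adjusted p = 0.080), and Arg1 at 24 h only, at least 1.25-fold lower with its forskolin channel not well above background. Relative to the median of all genes, median centring turned the direction of Vgf at 2, 4 and 48 h, of Gap43 and Fos at 48 h and of Fos, Nfil3 and Cebpd at 24 h. It brought Arg1 at 24 h to 0.00, and the other called values of these genes kept their direction. Pde4b did not pass the filter on dim probes.

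**Figure D1:**
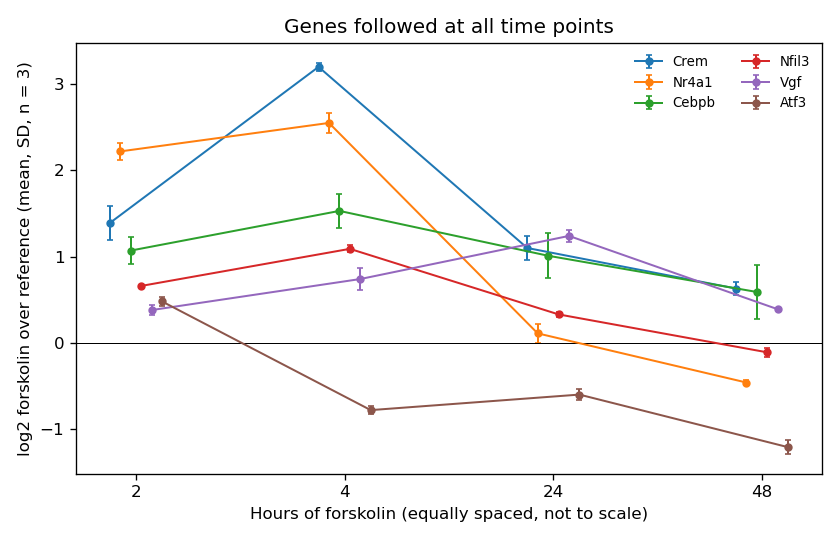
The plot gives the log2 ratio of forskolin over reference (vertical axis) against hours of forskolin (horizontal axis, equally spaced and not to scale) for 6 genes. Points are means and bars the SD of 3 arrays. Crem peaks at 3.20 and Nr4a1 at 2.55 after 4 h, Vgf peaks at 1.24 after 24 h, and Atf3 lies at -1.21 after 48 h.

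The 4 time points differed from each other in 9499 genes by a moderated F test (10514 with the slide as a block, 4506 with median centring). Between 2 and 4 h, Vip (2.29 ± 0.06, SE), Fst (2.21 ± 0.06), Crem (1.80 ± 0.09), the axon guidance gene Slit2 (1.61 ± 0.08) and the prostaglandin E synthase gene Ptges (1.33 ± 0.11) rose further. Klf10 (-2.50 ± 0.07), Id3 (-2.28 ± 0.07), Junb (-2.06 ± 0.10), Id1 (-1.92 ± 0.06) and Bbc3 (-1.75 ± 0.13) came down over the same step. From 4 to 24 h, Tmem204 (2.40 ± 0.11), Acox2 (2.29 ± 0.09), the nucleotide receptor gene P2ry6 (2.29 ± 0.07), Akr1b8 (2.19 ± 0.06) and Bbc3 (2.15 ± 0.13) rose. Rgs2 (-3.79 ± 0.06), Nr4a3 (-3.38 ± 0.09), Id4 (-3.19 ± 0.07), Tac1 (-2.45 ± 0.10) and Nr4a1 (-2.44 ± 0.08) came down. From 24 to 48 h, the angiopoietin gene Angpt2 (1.58 ± 0.07), Ltbp1 (1.31 ± 0.07), Rufy3 (1.28 ± 0.07), Pcp4 (1.27 ± 0.10) and Itpka (1.22 ± 0.07) rose. Fst (-2.47 ± 0.06), Vip (-1.75 ± 0.06), Egr1 (-1.33 ± 0.08), Id1 (-1.12 ± 0.06) and the ornithine decarboxylase gene Odc1 (-1.09 ± 0.09) came down. All of these differences had adjusted p-values of 3.8e-06 or smaller. The counts were 2799 genes between 2 and 4 h (996 higher at 4 h, 1803 lower), 6901 between 4 and 24 h (3734 higher at 24 h, 3167 lower) and 2655 between 24 and 48 h (1437 higher at 48 h, 1218 lower). With the slide as a block they were 3517, 7701 and 3364, and 99.7%, 99.6% and 99.7% of the called genes had the same sign on all 3 slides. With median centring they were 354, 3348 and 274, and 79.5% in place of 54.1% of the calls between 4 and 24 h were higher at 24 h.

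Late samples (24 and 48 h) differed from early samples (2 and 4 h) in 8969 genes, 4660 higher and 4309 lower, with 218 at least 2-fold higher and 160 at least 2-fold lower. The 2-fold counts were 841 and 597 with the processed signals, 456 and 313 with offset 0, and 228 and 98 with median centring. The largest rises from early to late were in Tmem204 (5.43-fold, 2.44 ± 0.08, SE), Ampd3 (1.96 ± 0.07), P2ry6 (1.90 ± 0.05), Slc7a8 (1.89 ± 0.06), the calcium pump gene Atp2b3 (1.85 ± 0.06), the desaturase gene Scd2 (1.85 ± 0.04), Lzts1 (1.84 ± 0.04) and Il17re (1.82 ± 0.04). Id4 (10.4-fold lower, -3.37 ± 0.05) and Id2 (-2.33 ± 0.05), inhibitors of basic helix-loop-helix factors, came down most together with Rgs2 (-3.19 ± 0.04), Nr4a3 (-2.93 ± 0.06), Nr4a1 (-2.56 ± 0.05), Hist1h2af (-2.09 ± 0.08), Hist1h2ao (-2.03 ± 0.08) and H2ac25 (-2.02 ± 0.05). The adjusted p-values of these 16 genes were 1.3e-10 or smaller. Of 25 early genes, 19 were lower late, 2 higher and 4 not called (median -0.90). In all, 22 were called when adjusted over the list alone (for the list, adjusted p = 5.8e-10, but adjusted p = 0.061 with an estimated correlation); Arc (0.92) and Homer1 (0.24) were the 2 that were higher. Of 41 cell cycle genes, 36 were lower, 2 higher and 3 not called (median -0.67). In all, 38 were called when adjusted over the list alone (for the list, adjusted p = 1.3e-16, and adjusted p = 0.010 with an estimated correlation). Of 29 cholesterol and fatty acid synthesis genes, 25 were higher, 1 lower and 3 not called (median 0.61). In all, 26 were called when adjusted over the list alone (for the list, adjusted p = 7.9e-12, and adjusted p = 0.010 with an estimated correlation), the largest being Msmo1 (1.81) and Hmgcs1 (1.64). Of 25 neuropeptide and secretory granule genes, 15 were higher, 3 lower and 7 not called (median 0.26, and 18 called when adjusted over the list alone). Their adjusted p was 0.017, but adjusted p = 0.23 with an estimated correlation. Of 34 genes of the neuronal cytoskeleton and synapse, 19 were higher, 6 lower and 9 not called (median 0.23, and 27 called when adjusted over the list alone). Their adjusted p was 0.013, but adjusted p = 0.20 with an estimated correlation. Th (1.26), Chga (1.1) and Chgb (1.09) rose in the former list against Tac1 (-1.97), and Mapt (1.44), Snap25 (1.04) and Prph (0.98) in the latter against Stmn1 (-0.89) and Nefl (-0.86). With the slide as a block 9690 genes were called, and 8912 of the 8969 (99.4%) had the same sign on all 3 slides. With median centring 5181 were called, of which 70.7% were higher late in place of 52.0%.

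**Figure D2:**
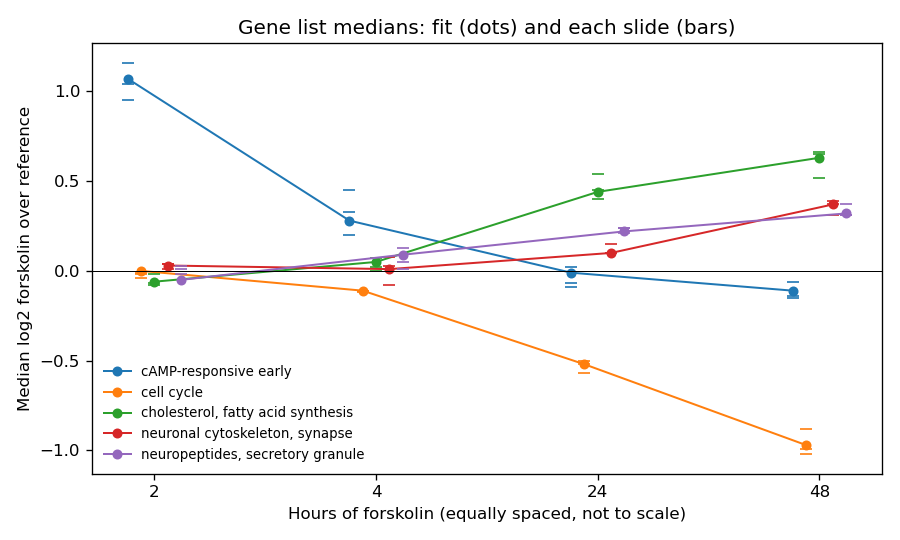
The plot gives the median log2 ratio of forskolin over reference (vertical axis) of 5 gene lists against hours of forskolin (horizontal axis, equally spaced and not to scale). Dots joined by lines are the medians of the fitted values and short bars the medians on each of the 3 slides. The early genes come down from 1.07 at 2 h to -0.11 at 48 h, the cell cycle median from 0.00 to -0.97, and cholesterol and fatty acid synthesis rises from -0.06 to 0.63.

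Of the 95 tests of 19 lists, 20 were called with the preset correlation, 9 with an estimated correlation and 20 with the slide as a block. The medians of the 20 called with the preset correlation had the same sign on all 3 slides, whose arrays also gave the calls. The remaining 10 lists were not called in any of their 5 tests, so no shift beyond other genes was found, which excludes neither a shift nor changes of members. Without the filter on dim probes 25 tests were called and without background correction 22. Among these 10 lists, that of ribosomal proteins gained calls in both settings and that of quiescence and FoxO targets without the filter. Of 22 cAMP pathway components, 11 rose and 6 fell at 48 h (median 0.13, smallest adjusted p = 0.070, and 17 called when adjusted over the list alone), with Adcy6 at 1.15 ± 0.09 and Akap5 at -0.65. Of 31 regeneration-associated genes, 14 rose and 7 fell at 48 h (median 0.06, smallest adjusted p = 0.35, and 21 called when adjusted over the list alone), with Vip, Tubb3 (0.74) and L1cam (0.56) against Atf3 and Klf6 (-0.90). Relative to all genes, median centring turned that median to -0.09 and L1cam to -0.27. Of 15 heat shock genes, 6 rose and 4 fell at 4 h (median -0.02, smallest adjusted p = 0.17, and 10 called when adjusted over the list alone), with the co-chaperone gene Bag3 at 1.00 ± 0.07 and Hspe1 at -0.20 ± 0.04. Relative to all genes the median was 0.02, but -0.42 with median centring. Of 13 actin, SRF and YAP targets, 3 rose and 8 fell at 48 h (median -0.20, smallest adjusted p = 0.074, and 12 called when adjusted over the list alone), with Vcl at -0.96 ± 0.06 and Actn1 at 0.67. With the processed signals the 48 h medians were -0.54 for this list, 0.32 for the cAMP pathway and 0.26 for the regeneration list, and relative to all genes the actin, SRF and YAP median was -0.59 with median centring. Of 18 quiescence and FoxO targets, 4 rose and 3 fell at 2 h (median 0.06, smallest adjusted p = 0.091, and 9 called when adjusted over the list alone), among them Sgk1 and Tob1, and without background correction the median was 0.03.

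Markers of other cell types were few and moved both ways. Of 5 glial markers that passed the filter, of 16 fixed, 1 rose and 3 fell at 48 h (median -0.16, smallest adjusted p = 0.31, and 4 called when adjusted over the list alone), and the glutamine synthetase gene Glul rose at 4 h (1.00 ± 0.04). Without background correction the glial median at 48 h was -0.06, and median centring turned it to 0.05 relative to all genes. Of 12 fibroblast and matrix markers, 4 rose and 4 fell at 48 h (median -0.07, smallest adjusted p = 0.26, and 9 called when adjusted over the list alone). Of 10 leukocyte and endothelial markers, 2 rose and 0 fell at 48 h (median -0.01, smallest adjusted p = 0.57, and 2 called when adjusted over the list alone), with Vwf at 0.98 ± 0.03. Of 47 ribosomal protein genes, 24 rose and 16 fell at 48 h (median 0.11, smallest adjusted p = 0.070, and 43 called when adjusted over the list alone). Rps23 (-0.67 ± 0.25), Rpl8 (-0.76 ± 0.11) and Rpl14 (-0.71 ± 0.04) lay below the reference by similar amounts at every time point. Relative to all genes, the median of the list was 0.12 at 48 h but -0.82 with median centring and 0.24 with the series matrix values. Of 14 housekeeping genes, 5 rose and 6 fell at 48 h (median 0.00, smallest adjusted p = 0.17, and 11 called when adjusted over the list alone), and relative to all genes the median was -0.78 with median centring. Actb fell by 1.1 (± 0.05) at 48 h, while Eef1a1 (1.05 ± 0.48) and B2m (0.90 ± 0.06) rose. B2m was at -0.17 at 48 h and Eef1a1 at -0.26 at 24 h with median centring, against a median of -0.46 and -0.45 for all genes.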

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

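The share of called genes that differ among times, the comparison of 48 h with 24 h for the early genes, the list medians under other scalings and the splits within slides were tests chosen after the results were seen. The comparison of probes of a gene and the splits over all arrays were chosen before.

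Gene lists differed between late and early samples by a test of the difference. The median difference was -0.90 for cAMP-responsive early genes (-0.87 with members dim on 1 side at their bound), -0.67 for the cell cycle, 0.61 for cholesterol and fatty acid synthesis, 0.26 for neuropeptides and the secretory granule and 0.23 for the neuronal cytoskeleton and synapse. With an estimated correlation the calls of the early genes (adjusted p = 0.061), neuropeptides (adjusted p = 0.23) and neuronal cytoskeleton (adjusted p = 0.20) were lost. Genes called above the reference at some time points and below it at others also differed between late and early: Nr4a1 by -2.56 (± 0.05, SE), Fos by -0.92 (± 0.05; at least 1.83-fold lower late), Nfil3 by -0.76 (± 0.04), Atf3 by -0.75 (± 0.04), Creb1 by -0.56 (± 0.05) and Gap43 by 0.20 (± 0.07), each with the same sign on all 3 slides. The arrays of these slides also gave the calls of those genes, so the shared sign adds no separate support. Spike-in control probes, outside the comparisons, followed their known ratios with slopes of 0.964 to 0.980.

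Many genes were called against the reference with small changes, 1861 of them in the same direction at all 4 time points and 1643 of those under 2-fold each time. As no dyes were swapped, an effect of the dye on single genes was weighed. Of 14052 genes called at any time point, 67.3% also differed among the time points, where such an effect cancels. Among all genes tested, called or not, 9499 of 17656 did. A constant dye effect alone cannot give such differences, but an offset together with a change over time would. The share therefore does not decide whether an offset lay behind the calls against the reference. Of the 1861 genes, 733 did not differ among the time points, as a constant dye effect would give, and for these it stays open. For the rest of the 1861 an offset beneath a change over time stays open too. Across 2325 genes, the correlation between 2 probes of a gene was 0.59 for the mean change over the 4 time points and 0.77 for late minus early. The ratio was 0.77 (bootstrap 95% interval 0.70 to 0.85), which argues against a probe-bound dye effect as the main source of the shared change over these genes together. Genes with large changes weigh most in such a correlation, so it does not decide for the small changes. Nor can it detect a dye effect that the probes of a gene share. A dye effect stays open for single genes: 20 of 47 ribosomal protein genes were called in the same direction at all 4 time points, 13 of them with no difference among times, and no biological explanation was tested for these.

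Of 25 cAMP-responsive early genes, 13 were below the reference at 24 or 48 h. A constant dye offset over genes back at their starting level would give the same value at both times. Of the 13, 7 (Junb, Egr1, Nr4a1, Ier2, Atf3, Nfil3 and Klf4) were lower at 48 h than at 24 h, so their values still changed. A rise still fading at 24 h over such an offset would also give this, and Nfil3 lay above the reference at 24 h. The comparison therefore cannot decide whether an offset put these 7 below the reference. For the other 6 (Fos, Fosb, Jun, Egr4, Arc and Homer1) a dye offset cannot be told apart from a change, for want of swapped dyes. Whether the reference was taken while these genes still responded to the medium change cannot be told, since 0 arrays held unstimulated cells at 24 or 48 h; the effect of forskolin itself stays among the open explanations.

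Cell cycle genes were lower and cholesterol and fatty acid synthesis genes higher at 24 and 48 h. Relative to all genes, the smallest late minus early median under 4 other scalings was -0.57 for the cell cycle and 0.56 for cholesterol and fatty acid synthesis. This argues against the choice among these scalings as the source of the late minus early differences. The setting without background correction kept the loess step, and the processed signals had a lowess step of their own. Values relative to all genes cannot show a shift shared by all genes. Hours in low serum rose together with hours of forskolin, and with 0 arrays of unstimulated cells at 24 or 48 h they cannot be told apart.

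Other splits of the arrays bear on whether chance could give such counts. For the F test, 1 of 100 splits of the 12 arrays into 4 groups, the real one with 9499 genes, gave as many, and the highest other gave 1701. For late against early, 1 of 100 splits, again the real one with 8969 genes, gave as many and the highest other gave 2082. A share of 1 in 100 is the smallest that 100 splits can give. It argues against a random grouping of these arrays for both counts. Arrays of a time point that were alike through a shared culture or array position would give it too. When arrays changed groups only within their slide, again 1 of 100 splits, the real one, gave as many, and the highest others gave 7042 for the F test and 4513 for late against early. For successive time points the 10 splits of 6 arrays are too few for a share under 0.05: the real counts were 2799, 6901 and 2655, each reached by 1 split, and the highest other was 0 in each.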

How the results depend on the processing

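All alternatives were chosen before the data were examined. Apart from those given here, counts of called genes stayed within 1.5 times of those reported, whereas counts at 2-fold moved further and are given wherever the report prints them. Of the genes named, 213 values were followed, but 192 with the series matrix values, 187 with the stricter filter and 197 on the compared arrays alone. Among those called in either fit, none changed direction outside median centring. Over all genes, up to 21 genes called in both fits did so, at 4 h with the mean of all probes. Many signals lay near background: on each array 19889 to 21973 of the 43379 non-control spots were well above background in the forskolin channel, and changes of the others are compressed.

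With median centring in place of loess, the counts of called genes moved to 13759 at 2 h, 13903 at 4 h, 354 between 4 and 2 h, 3348 between 24 and 4 h, 274 between 48 and 24 h, 5181 for late against early and 4506 among the 4 time points. For the counts against the reference the construction of this setting shows the cause, since it leaves in place the trend of the log2 ratio with brightness. A trend shared by all arrays would cancel between time points. The trend differed between arrays (-1.12 to -1.72 for bright against dimmer probes), but its part in the lower counts between time points was not tested. Of the 213 gene values put through median centring, 29 changed direction, before the shift of all genes is taken off. At 2 h these were Atf3 (-0.48), Creb1 (-0.39), Nfil3 (-0.40) and Vgf (-1.19). At 4 h they were Aars1 (-0.58), Bag3 (-0.14), Creb1 (-0.55), Csnk1d (0.00), Hspb8 (-0.51), Nfil3 (-0.01), Rpl4 (-0.54), Tfrc (-0.49) and Vgf (-0.73). At 24 h they were Aldoa (-0.17), Cebpd (-0.64), Eef1a1 (-0.26), Gadd45a (-0.11), Hspa8 (-0.63), Nfil3 (-0.57), Nr4a1 (-0.81), Prkar1a (-0.48), Vgf (-0.24) and Vim (-0.50). At 48 h they were B2m (-0.17), Cebpb (-0.35), Chgb (-0.05), Crem (0.00), Gap43 (-1) and Vgf (-1.12). Other values given that turned include those at 2 h of Bhlhe40 (-0.33), Pdia3 (-0.67) and Calr (-0.75), at 4 h of Btg2 (-0.02) and Id2 (-0.65), at 24 h of Atf5 (-0.15), Bambi (-0.36), Ccnd3 (-0.35), Cdc25b (-0.01), Eno2 (-0.30) and Slc2a1 (-0.15), and at 48 h of Actn1 (-0.11), Eef1a1 (-0.32), L1cam (-0.74), Prph (-0.61), Runx1 (-0.19) and Tubb3 (-0.42). A further 6 of the 213 values kept their direction but lost their call under it, namely Cebpb at 2 h (0.01) and 24 h (0.09), Glul (0.01) and Runx1 (0.16) at 4 h, Ddit3 at 24 h (0.04) and Atf5 at 48 h (0.15), and 7 gained a call.

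With an estimated inter-gene correlation, 9 of the 20 list calls were kept; the cause was not tested. Without the filter on dim probes 25 list tests were called, and without background correction 22. Leaving out an array gave 2821 to 5539 genes at 2 h (lowest without 2 h replicate 3; 3188 without 2 h replicate 2), 7135 to 9209 at 4 h, 7833 to 9853 at 24 h, 8772 to 10286 at 48 h, 1872 to 3114 between 4 and 2 h, 5960 to 7222 between 24 and 4 h, 1884 to 2747 between 48 and 24 h, 8420 to 8940 for late against early, 8788 to 9554 among times and 20 to 22 list calls; 11 of 2556 values of named genes lost their call and 1 gained it. Nfil3 at 48 h also lost its call with offset 0 (adjusted p = 0.088), with the processed signals (0.055), without the filter on dim probes (0.073) and on the compared arrays alone (0.11), and Creb1 at 4 h without that filter (0.052).

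The replicate number, here the same as the slide, as a block gave 6221, 9697, 10334 and 10929 genes at 2, 4, 24 and 48 h, 3517, 7701 and 3364 between successive times, 9690 for late against early, 10514 among times and 20 list calls; it changed the call of 1 named gene value, Nr4a1 at 24 h. Samples of the same number correlated in their deviations at 0.05 to 0.48 (median 0.23, 14 of 18 pairs over 0.1), against a median of -0.21 for different numbers. Of 12 arrays, 7 correlated best with their own number. As not every pair was over 0.1, the numbers were not taken to pair the samples. This rule does not show that slides had no effect, since all 18 pairs were above 0. The p-values and SEs given leave the slide out unless it is named as a block.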

Other observations

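The families described here were chosen after their values were seen, so no test of their shift is given. Core histone genes, as 15 genes with symbols of that family, were mostly lower late: 13 fell at 24 h, 8 of them at least 2-fold, and 12 fell at 48 h, 9 of them at least 2-fold, while at 2 h 2 rose and 5 fell, and at 4 h 6 rose and 2 fell. The median was -1.01 at 24 h and -1.08 at 48 h (late minus early -1.26), and it stayed below that of all genes late minus early under 4 other scalings. With the series matrix values it was smaller, at -0.54, -0.57 and -0.72. Those values are missing for some genes, with 192 of 213 gene values followed there. That median may therefore rest on fewer members and is not a like comparison. Besides the H2A genes named among the largest falls, Hist1h4m (-1.63 at 48 h), Hist1h4b (-1.60) and Hist1h2bg (-1.08) fell. The H2A gene H2ac1 (-0.13), H4c14 (-0.14) and Hist3h2ba (0.07) were not called at 48 h. Some of these genes are near-identical copies within a histone class, so not all members are independent.

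The 4 Id genes, whose products bind and inhibit basic helix-loop-helix factors and which BMP signalling is known to induce, rose at 2 h (Id4 2.07, Id1 1.82, Id2 1.75, Id3 1.35). At 4 h they had parted, with Id4 at 2.21, Id2 at 0.47, Id1 at -0.11 and Id3 at -0.92 (Id2 turned to -0.06 relative to all genes with median centring), and at 48 h all 4 were lower (-1.49 for Id4 and Id2, -1.37 for Id3 and -0.94 for Id1). Smad7, an inhibitor of TGF-beta signalling, stood at 1.11 at 2 h and -1.21 at 48 h, and Bambi, a decoy receptor gene of the same pathway, at 2.14, 2.46, 0.60 and 0.02 at 2, 4, 24 and 48 h, whereas Smad6, also an inhibitor, was called at no time point (0.14, 0.06, 0.02 and -0.06). Of 33 genes with symbols of the voltage-gated calcium, potassium and sodium channel families, 2 rose and 5 fell at 2 h and 18 rose and 1 fell at 48 h (late minus early median 0.23). With the processed signals that median was 0.44. Membership rests on the symbol, so subunit genes such as Cacng3 (0.29) and Cacng7 (0.23), both among the 18, may not serve such channels. Cacna1b (1.29), Cacnb1 (1.22) and Scn9a (1.05) rose most at 48 h, and Kcnh1 (-1.16) and Scn3b (-1.13) had fallen at 4 h.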
